A study of Mus musculus with 3 samples.

How the data were processed

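Cells positive for c-Kit and negative or low for lineage markers were sorted from the cranial dura, the femur and the skull of 10 C57BL/6 mice aged 8 to 12 weeks, per the labels' protocols. The mice were perfused through the heart, leukocytes were freed mechanically, cells of the same site were pooled, and DAPI-negative singlets entered 10x Genomics droplets with the v3.1 kit for 3' ends. Libraries were sequenced on a NovaSeq 6000 at over 90% saturation, per the labels. The deposited values are integer counts of unique molecular identifiers (UMIs) per gene and cell barcode, per the file headers. The file headers name Cell Ranger 6.1.2 and the submitters' processing notes name Cell Ranger 6.0.0 and Seurat 4.0.4. Genome build, annotation and the rule by which barcodes were kept are not given in the sources used here, so no coordinates are printed and genes carry the symbols of the deposited files. The lowest deposited barcode held 500 UMIs in each library.

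Each site is 1 library, so the design has no replicates. No test between sites was made, and no p-value or standard error is given. CPM are UMIs scaled to the total UMIs of the cells summed, with exact Poisson 95% intervals, and shares of cells carry exact Clopper-Pearson 95% intervals. Intervals and lower bounds cover counting error only, not differences between mice, sorts or library preparations. A count of 0 is given the upper limit that 3 counts allow, which was 0.0873 CPM for the whole dura library, 0.0414 CPM for femur and 0.0523 CPM for skull. Folds given as at least a value divide the CPM read in the higher library by the limit for a count of 0. They leave out the counting error of the higher library. Among the genes named, the widest distance from the CPM to its interval bounds, averaged over both bounds, in the higher library was 3.62% of the CPM over whole libraries, 37.6% within classes and 10.3% within HSC/MPP-like cells.

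Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. The gene minimum left out 287 dura barcodes, 344 femur barcodes and 1891 skull barcodes, and the mitochondrial limit left out 69, 95 and 98 further ones. Doublets were scored with Scrublet. Its automatic threshold called 7, 0 and 1 barcodes in the dura, femur and skull libraries, which is too few for their sizes, so the barcodes with the highest scores were removed at 0.8% per 1000 barcodes. That removed 34 dura, 1174 femur and 193 skull cells that had passed the other filters. The kept cells numbered 2081, 10561 and 3167.

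Kept cells of the 3 libraries were clustered together with scanpy 1.11.5 on counts scaled to 10000 per cell and log-transformed, using 2000 variable genes without cell cycle genes, Xist, Tsix and Y-linked genes. The settings were 30 principal components, 15 neighbours, Leiden resolution 1, seed 0 and no batch correction. A cluster was named X-like when at least 3 markers of 1 of 19 fixed marker classes stood among its 30 leading genes by fold. It stayed unnamed when markers of another class led its top 10 or when markers were tied. The marker lists were fixed before the data were examined, whereas the scoring rule was set after the clusters had been seen. The named classes therefore depend on a rebuilt annotation.

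UMIs were summed over all kept cells of a library, and over the cells of each class that had at least 50 cells in both libraries of a pair. The log2 ratio was taken after adding 5 CPM to both sides. Genes were named by a rule: of genes with at least 50 CPM and 30 UMIs in 1 library, the 10 highest and the 10 lowest log2 ratios per pair of libraries. Within classes the rule took the 5 highest and 5 lowest with at least 100 CPM. Gene models without a symbol of their own and mitochondrial genes were left out of that rule. Of 17 gene lists, members with at least 10 UMIs over the pair counted as measured, and a member was called higher or lower at 2-fold. The lists were immediate-early and dissociation stress, heat shock, NF-kB and inflammatory cytokines, type I interferon response, MHC class II presentation, MHC class I presentation, G1/S, G2/M, quiescence, niche adhesion and homing, glycolysis, nuclear-encoded oxidative phosphorylation, hypoxia, cholesterol synthesis, haem synthesis and iron uptake, cytosolic ribosomal proteins, and mitochondrially encoded genes. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. Of the symbols in the lists and marker classes, 5 were absent from the 32285 genes of the deposited files. Examples from a list are its members with the most UMIs.

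Shares of cells with a Mki67 or Top2a UMI were taken after thinning each cell to 2000 UMIs, leaving out shallower cells. The comparisons, filters, gene lists, markers and most alternative settings were fixed before the data were examined. The alternatives were trimmed-mean scaling with edgeR 4.0.16 (TMM), median-of-ratios scaling, 1 CPM added, no minimum for list members, means over cells, other cell filters, no doublet removal, resolutions 0.5 and 2, cycle genes kept, equal cells per library, each library clustered alone, a class from each cell's marker score, classes weighted equally, and thinning to 1000 UMIs or none. Alternatives chosen after seeing the data left out single clusters, the stromal-like cells, or interferon genes from the clustering.

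The calculations were tested on simulated data with 200 changed genes, drawn as Poisson counts from the femur means at the dura and femur depths. Both sides shared the femur means apart from the set changes. The test therefore covers the calculation steps, not variation between cells or differences in the mix of cells. Of 100 genes changed 3-fold, 99% were called at 2-fold and 100% had the right direction. Of 100 genes changed 1.5-fold, 1% were called and 100% had the right direction. None of the 2443 unchanged genes was called. Poisson intervals held the true value for 95.4% of 2656 genes. A doubled interferon list of 24 genes gave a median of 0.90 at percentile 100, and an unchanged G2/M list of 52 genes gave -0.04 at percentile 74.5. Binomial intervals over 1000 draws of 2000 cells held a true share of 5% in 96.8% of draws and one of 30% in 95.4%. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.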

Results

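Single-cell RNA sequencing measured the transcriptomes of sorted c-Kit-positive, lineage-low cells from 3 mouse sites: the cranial dura, which is the outer membrane around the brain, the marrow of the femur and the marrow of the skull. Each site was 1 pooled library, and the labels give 10 mice. The study's title places haematopoietic progenitors of these sites side by side, so each pair of sites was compared. The dura library held 2471 barcodes and 35588319 UMIs, the femur library 12174 barcodes and 88496399 UMIs, and the skull library 5349 barcodes and 61774519 UMIs. After filtering, 2081 dura, 10561 femur and 3167 skull cells remained, with 34356317, 72538137 and 57364115 UMIs. Median depth per kept cell was 10126 UMIs in dura, 6427 in femur and 12204 in skull. The filters kept 84.2% of dura, 86.8% of femur and 59.2% of skull barcodes. The median mitochondrial share was 2.14% in dura, 3.40% in femur and 0.595% in skull.

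Kit, the receptor used for the sort, was read at 109 CPM in dura (106 to 113), 97.7 CPM in femur (95.4 to 99.97) and 85.0 CPM in skull (82.6 to 87.4). Ms4a1, Klrb1c and Cd3e, genes of mature lymphocytes, were higher in the dura library than in both marrow libraries. Ms4a1, which encodes CD20 of B cells, stood at 15.2 CPM in dura, 0.0965 CPM in femur and 0.715 CPM in skull. Klrb1c, a receptor of natural killer cells, stood at 16.4, 0.662 and 0.628 CPM. Cd3e of the T cell receptor complex stood at 2.82 CPM in dura and 0.0827 CPM in femur, and no UMI was counted in skull, which allows up to 0.0523 CPM. Cd4 of helper T cells stood at 0.437 CPM in dura (0.244 to 0.720), 0.276 CPM in femur (0.168 to 0.426) and 0.209 CPM in skull (0.108 to 0.365), with overlapping intervals. Itgam, a myeloid lineage marker, lay between 6.17 CPM in dura and 9.20 CPM in skull.

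The 3 libraries differed in their mix of cell classes. T/NK/ILC-like cells, a class of T cells, natural killer cells and innate lymphoid cells, made up 27.3% of dura cells (25.4 to 29.3), 0.473% of femur cells (0.352 to 0.624) and 0.474% of skull cells (0.265 to 0.780). Dendritic-like cells made up 17.7% of dura, 0.294% of femur and 1.11% of skull cells, and B lineage-like cells 9.61%, 2.72% and 0.853%. Monocyte lineage-like cells made up 3.27% of dura cells (2.55 to 4.12), 24.2% of femur cells (23.4 to 25) and 7.20% of skull cells (6.32 to 8.16). HSC/MPP-like cells, which carry markers of haematopoietic stem cells and multipotent progenitors, numbered 142 in dura, 1650 in femur and 601 in skull. They were 6.82% (5.78 to 7.99), 15.6% (14.9 to 16.3) and 19.0% (17.6 to 20.4) of the kept cells.

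Other haematopoietic classes were found in all 3 libraries. Erythroid lineage-like cells made up 5.33% of dura, 15.6% of femur and 7.55% of skull cells. Granulocyte-monocyte progenitor-like cells made up 2.35%, 13.4% and 38.7%, megakaryocyte lineage-like cells 1.39%, 4.34% and 3.85%, and lymphoid-primed MPP-like cells 1.49%, 4.28% and 0.60%. Basophil lineage-like cells made up 4.32% of dura cells (3.49 to 5.29), 1.84% of femur cells (1.59 to 2.11) and 2.87% of skull cells (2.32 to 3.52). Neutrophil precursor-like cells made up 0.240%, 0.369% and 1.48%, and macrophage-like cells numbered 5, 1 and 52. Stromal-like cells, led by Ptgds, Mgp and Igfbp5, made up 6.15% of dura cells. The femur library had 0 of them, which allows up to 0.0284%, and the skull library had 1.

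The clustering settings moved these shares. The sort and a depth gap may also bear on them, which was not tested. Kit was read at 163 CPM in the T/NK/ILC-like cells of dura, 78.4 CPM in its dendritic-like cells, 48.7 CPM in stromal-like cells and 197 CPM in its HSC/MPP-like cells. HSC/MPP-like cells had median depths of 18642 UMIs in dura, 3369.5 UMIs in femur and 13709 UMIs in skull. Different clusters held them: 135 of the dura cells and 580 of the skull cells lay in cluster 8, which Ccl4 led, while 1162 femur cells lay in cluster 29 and 463 in cluster 7, which interferon genes led. With interferon genes left out of the clustering the femur share was 14.9%, and over all alternatives the shares ranged from 4.52% to 8.46% in dura, 1.92% to 19.1% in femur and 9.35% to 29.6% in skull, so dura lay below skull in these settings while the place of femur is not settled. The granulocyte-monocyte progenitor-like share in skull rested on cluster 16 with 996 cells and ranged from 1.48% to 58.0% over the alternatives, while in femur it ranged from 0.0481% to 27.3%. The shares of lymphoid-primed MPP-like and megakaryocyte lineage-like cells also moved by more than 1.5 times in every library, and those of monocyte lineage-like cells ranged from 10.1% to 26.95% in femur, 0.758% to 11.2% in skull and 0% to 3.80% in dura. The erythroid lineage-like share of skull ranged from 3.09% to 30.1%, and basophil lineage-like cells reached 3.74% of femur and 6.32% of skull cells with classes from each cell's marker score. The dendritic-like share of dura was 10.8% when that library was clustered alone, and neither marrow library then held T/NK/ILC-like or dendritic-like cells. In skull the B lineage-like share ranged from 0.625% to 1.39%, and the dendritic-like and T/NK/ILC-like shares reached 1.72% and 0.758%. The erythroid lineage-like share of femur reached 25.5%, the basophil lineage-like share of dura fell to 2.74% with that library clustered alone, and the granulocyte-monocyte progenitor-like share of dura was then 0.

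Several clusters had no name by the fixed markers. Clusters 18 and 20 shared 8 of their 10 leading genes, among them Csrp3 and Clec4d. Cluster 18 held 3.08% of dura, 0.0663% of femur and 7.36% of skull cells, and cluster 20 held 10.2% of femur cells with 2 dura and 12 skull cells. Cluster 24, led by Pf4 and histone genes, held 2.69%, 6.55% and 6.25%. Cluster 26, led by Mgarp, Chgb and Map1b, and cluster 27, led by Ttr, Enpp2 and Mt3, held 119 and 45 dura cells and 0 cells of the marrow libraries, which allows up to 0.0284% in femur and 0.0947% in skull. Cluster 27 had 0.00227% of its UMIs from Malat1, against 1.29% in the dura library, and Xist was found in 1 of its 45 barcodes. Its median mitochondrial share was 1.32%. Whether the barcodes of cluster 27 were intact cells was not tested. Cluster 9 held 20 skull cells.

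**Figure D1:**
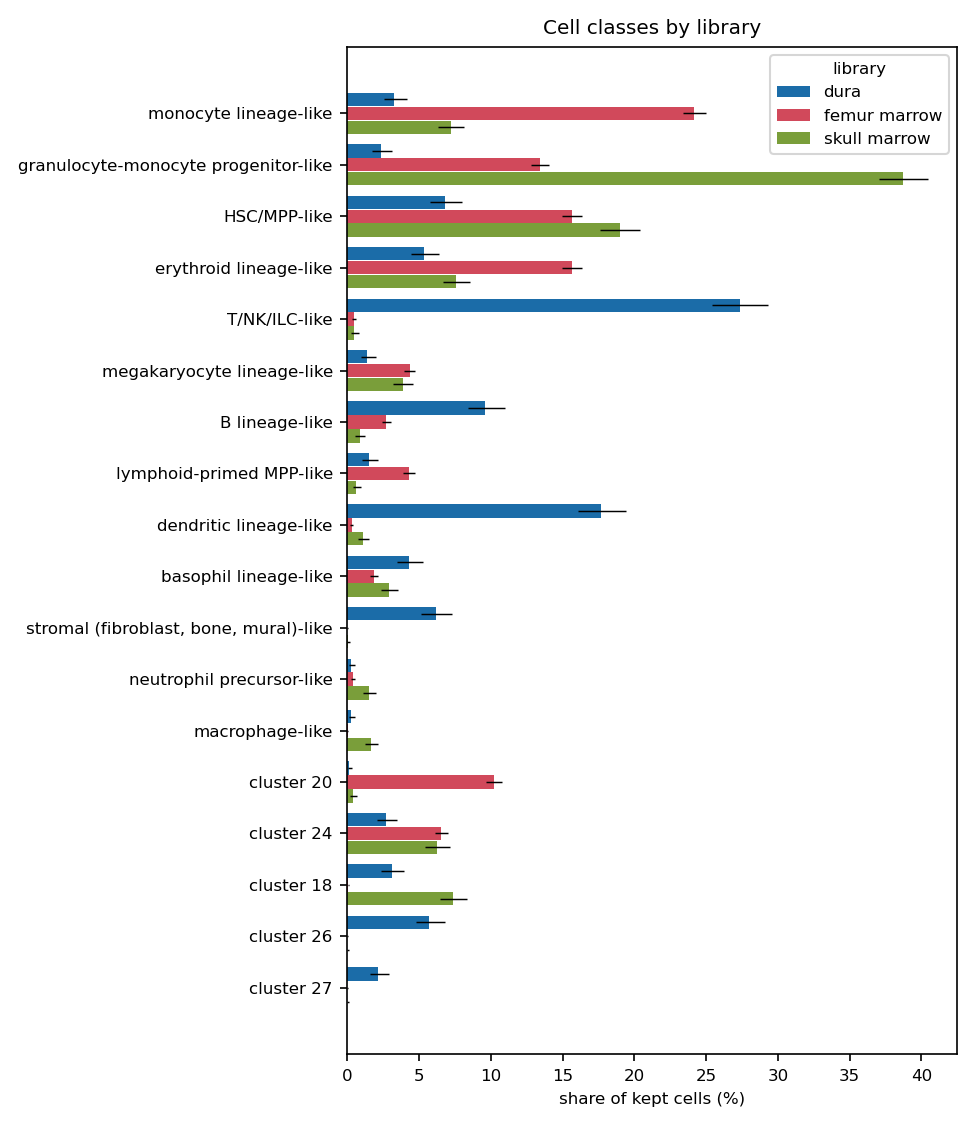
Percent of the kept cells of each library in each named class and in unnamed clusters 18, 20, 24, 26 and 27, with exact binomial 95% intervals. T/NK/ILC-like cells take 27.3% of the dura library and under 0.5% of both marrow libraries.

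The dura and femur libraries differed in MHC class II genes, in interferon-stimulated genes and in single genes such as Ttr, Ptgds and Mgp. MHC class II genes, which present peptides to helper T cells, were higher in dura: Cd74 stood at 3296 against 18.5 CPM, H2-Aa at 1424 against 7.83 CPM, H2-Eb1 at 1129.9 against 5.18 CPM and H2-Ab1 at 1507 against 28.4 CPM. Ttr, the transthyretin gene of the choroid plexus, was read at 2597 CPM in dura with no UMI in femur, at least 62794-fold higher. Ptgds, a prostaglandin synthase of the meninges, stood at 995 against 1.06 CPM, and Mgp, a matrix protein, at 363 CPM against 0.0276 CPM (2 UMIs, 0.00334 to 0.0996). Femur was higher in interferon-stimulated genes, such as Isg15 at 298 against 32.4 CPM, and in Mpo, the myeloperoxidase of granules, at 3308.5 against 806 CPM.

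The remaining genes that the naming rule took as higher in dura than femur were Ckb (log2 ratio 5.33), Plbd1 (5.20) and Jchain (5.18), which encodes the joining chain of antibodies. The remaining lower ones were Oasl2 (-2.65), Rsad2 (-2.61), Ifi44 (-2.54), Ifit1 (-2.40), Ly6c2 (-2.29), Rnf213 (-2.08), Ifitm3 (-2.06) and Rtp4 (-2.00). Ly6c2 encodes a surface protein of monocytes, and the others are known interferon-stimulated genes. The whole-library contrasts of Ttr, Ptgds and Mgp rested largely on the stromal-like cluster, which Ptgds and Mgp lead, and on cluster 27, which Ttr leads. Cluster 27 had few Malat1 UMIs, so the Ttr fold may rest on barcodes that were not intact cells, which was not tested. Without stromal-like cells and clusters 26 and 27 the log2 ratios were 2.06 for Ttr, 2.0 for Ptgds and 1.05 for Mgp.

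All 7 measured MHC class II genes were at least 2-fold higher in dura than in femur, with a median log2 ratio of 5.50 at percentile 100 among random lists. The type I interferon list, genes induced by interferon alpha and beta, had 16 of 24 members lower in dura and none higher, with a median of -1.31 at percentile 0. Immediate-early and dissociation stress genes, which respond within minutes to handling, had 13 of 23 members higher and a median of 1.17, with Junb at 115 against 26.9 CPM and Jund at 167 against 49.7 CPM. Quiescence-associated genes had 6 of 14 members higher and a median of 0.88, with Txnip at 241 against 84.9 CPM and Btg1 at 148 against 35.8 CPM. NF-kB and inflammatory genes had 5 of 18 higher and 1 lower, with a median of 0.57 and Nfkbia at 104 against 47.6 CPM. The mitochondrially encoded list had a median of -0.49 and no member at 2-fold, with mt-Co3 at 3459 against 6841 CPM, while median mitochondrial shares per cell were 2.14% and 3.40%.

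The other lists lay closer to 0 between dura and femur. Medians were 0.27 for hypoxia, 0.13 for niche adhesion and homing, 0.10 for cholesterol synthesis, -0.06 for haem synthesis, -0.12 for heat shock, -0.13 for G2/M, -0.18 for ribosomal proteins, -0.21 for MHC class I, -0.22 for glycolysis and -0.26 for G1/S genes. In these lists, 1 hypoxia gene, 2 niche genes and 1 heat shock gene were higher at 2-fold and none was lower. Oxidative phosphorylation had a median of 0.01, which became -0.14 with TMM and -0.15 with median-of-ratios scaling. Cholesterol synthesis turned to -0.07 and haem synthesis to 0.13 with classes weighted equally, and without stromal-like cells and clusters 26 and 27 hypoxia turned to -0.0056 and oxidative phosphorylation to -0.07. MHC class I lay farther from 0 with classes weighted equally, at -0.55. The median of all genes was -0.06 by CPM and -0.21 under both other scalings.

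These whole-library differences carry the mix of classes. Equal weights were given only to classes with at least 50 cells in both libraries, so for dura over femur they leave out the dendritic-like, stromal-like and granulocyte-monocyte progenitor-like cells and the unnamed clusters rather than balance them. With classes weighted equally the dura over femur median was 0.10 for MHC class II, 0.31 for immediate-early genes, 0.14 for quiescence-associated genes and -1.69 for interferon genes, and H2-Ab1, Ckb and Plbd1 turned to -0.15, -0.17 and -0.09. Cd74, H2-Aa, Mpo and Ly6c2 were then at 1.41, 0.32, -0.73 and -0.93, and Ttr, Ptgds, Mgp, H2-Eb1 and Jchain at 2.24, 1.42, 1.41, 0.27 and 4.88. As means over cells the G2/M median was -0.73 in place of -0.13.

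The dura and skull libraries differed in MHC class II genes and in single genes such as Ttr, Ptgds and Mgp and, in the other direction, Prtn3 and Elane. Cd74 stood at 3296 CPM in dura and 157 CPM in skull, H2-Aa at 1424 and 67.4 CPM, and H2-Eb1 at 1129.9 and 41.1 CPM. Ttr stood at 2597 and 0.122 CPM, Ptgds at 995 and 1.69 CPM, and Mgp at 363 and 1.41 CPM. Prtn3, Elane and Ctsg, which encode neutrophil granule proteases, were higher in skull, at 5289 against 1320.2 CPM, 4240.5 against 984 CPM and 2627 against 881 CPM. Xist, the RNA that silences an X chromosome in female cells, stood at 653 CPM in dura and 0.105 CPM in skull.

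Further genes named as higher in dura than skull were Ecrg4, which had no UMI in skull and was at least 2090.4-fold higher, Id3 (log2 ratio 4.47) and Ckb (4.37). Without stromal-like cells and clusters 26 and 27 the log2 ratios were 2.03 for Ttr, 1.86 for Ptgds, 1.0 for Mgp, 0.34 for Ecrg4, 1.69 for Id3 and 3.84 for Ckb. They were, with classes weighted equally, 1.86 for Ttr, 0.65 for Ptgds, 0.97 for Mgp, 0.25 for Ecrg4, 0.22 for Id3 and 0.39 for Ckb. Further lower ones were Dmkn (-2.10), Ms4a3 (-2.08), Hp (-2.01), Prss57 (-1.79), Cebpe (-1.77), Trem3 (-1.76) and Mpo (-1.75). Cebpe encodes a transcription factor of granule formation, and Cebpe, Ms4a3, Prss57 and Trem3 are among the genes that lead the granulocyte-monocyte progenitor-like clusters. Skull cluster 16, with 996 cells, belongs to that class. With classes weighted equally the log2 ratios of Elane, Prtn3, Mpo and Ctsg were -0.96, -0.75, -0.46 and -0.06, and those of the other lower genes lay between -1.04 for Dmkn and -0.67 for Hp. That setting leaves out the granulocyte-monocyte progenitor-like cells, skull cluster 16 included, because dura had 49 of them.

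All 7 MHC class II genes were higher in dura than skull, with a median of 3.96. That median became -0.11 with classes weighted equally, which leaves out the dendritic-like and B lineage-like cells, and Cd74, H2-Aa and H2-Eb1 turned to -0.16, -0.01 and -0.08. Mitochondrially encoded genes had 11 of 13 members higher in dura and a median of 1.51, with mt-Atp6 at 3767 against 1397 CPM, beside median mitochondrial shares of 2.14% and 0.595%. Quiescence-associated genes had 3 of 14 higher and a median of 0.82, which was -0.02 with classes weighted equally. The interferon list had 5 of 24 higher and a median of 0.53, with Ifi27l2a at 96.0 against 9.94 CPM. Immediate-early genes had 5 of 23 higher and 2 lower, with a median of 0.44 that became -0.27 with classes weighted equally, and NF-kB genes had 3 of 19 higher, with a median of 0.40 that became -0.03.

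Other medians between dura and skull were 0.38 for haem synthesis, 0.36 for MHC class I, 0.19 for hypoxia, -0.06 for niche adhesion, -0.07 for oxidative phosphorylation, -0.12 for G2/M, -0.20 for ribosomal proteins, -0.26 for G1/S, -0.39 for heat shock and -0.42 for glycolysis. At 2-fold, 2 niche genes and 1 heat shock gene were higher and 1 glycolysis gene was lower in dura. Hsp90ab1, a chaperone, stood at 2446 against 4021 CPM and Pgam1 of glycolysis at 261 against 542 CPM. Cholesterol synthesis had a median of 0.09, which became -0.04 with TMM and -0.06 with median-of-ratios scaling. With classes weighted equally MHC class I turned to -0.03, G1/S to 0.09, G2/M to 0.02, niche adhesion to 0.12 and cholesterol synthesis to -0.01. As means over cells haem synthesis turned to -0.18 and niche adhesion to 0.14, and without clusters 16 and 31 oxidative phosphorylation turned to 0.01. The median of all genes was -0.13 by CPM, -0.29 with TMM and -0.32 with median-of-ratios scaling.

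The marrow libraries of skull and femur differed in interferon-stimulated genes and in single genes such as Xist, Igkc and S100a8. Isg15 stood at 12.4 CPM in skull and 298 CPM in femur, Irf7, a transcription factor of the interferon response, at 5.13 and 97.7 CPM, and Ifit1 at 1.41 and 58.8 CPM. S100a8 and S100a9, the calprotectin genes of neutrophils, were higher in skull at 1173 against 283 CPM and 1184 against 309 CPM, and Camp, an antimicrobial peptide, at 361 against 84.8 CPM. Igkc, an antibody light chain, stood at 844 against 59.8 CPM. Xist stood at 0.105 CPM in skull and 964 CPM in femur.

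Further genes named as higher in skull than femur were Jchain (log2 ratio 3.01), Cd74 (2.79), Prss34 (2.77), H2-Aa (2.5), Ngp (1.94) and Chil3 (1.76). Camp, Ngp, S100a8 and S100a9 lead the neutrophil precursor-like cluster, which held 1.48% of skull and 0.369% of femur cells. As means over cells their log2 ratios were 0.96 for Camp, whole library, and 0.89 for Ngp, against 2.03 and 1.94. With classes weighted equally S100a8, S100a9, Camp, Ngp and Chil3 had 1.09, 1.75, 1.67, 0.27 and 1.07, and Igkc, Jchain, Cd74, Prss34 and H2-Aa had 2.65, 0.71, 0.99, 1.69 and 0.51, without the neutrophil precursor-like, B lineage-like and dendritic-like cells, which were under 50 in a library. Further lower ones were Ifi27l2a (-3.06), Rsad2 (-2.98), Ifi44 (-2.97), Oasl2 (-2.97), Zbp1 (-2.73) and Rtp4 (-2.28). With 1 CPM added in place of 5 the ratios of genes with few UMIs in 1 library were larger in size, such as -4.63 in place of -3.31 for Ifit1.

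The interferon list had 21 of 24 members lower in skull than femur and none higher, with a median of -1.93 at percentile 0. Mitochondrially encoded genes had 12 of 13 lower and a median of -1.71, beside median mitochondrial shares of 0.595% in skull and 3.40% in femur. Immediate-early genes had 9 of 23 higher and a median of 0.76, with Junb at 64.7 against 26.9 CPM. MHC class II genes had 4 of 7 higher and a median of 1.54, which was 0.42 with classes weighted equally. MHC class I genes had 3 of 10 lower and a median of -0.47, with B2m at 710.4 against 956 CPM. Other medians were 0.27 for glycolysis, 0.25 for heat shock, 0.15 for hypoxia, 0.15 for cholesterol synthesis, 0.11 for NF-kB genes, 0.10 for niche adhesion, 0.10 for quiescence-associated genes, -0.03 for G1/S, -0.04 for G2/M and -0.29 for haem synthesis. At 2-fold, 1 NF-kB gene was higher and 1 was lower. Haem synthesis turned to 0.04, G1/S to 0.07 and G2/M to 0.08 with classes weighted equally. Without clusters 16 and 31 G1/S turned to 0.10, G2/M to 0.07, oxidative phosphorylation to -0.03 and ribosomal proteins to -0.06. Oxidative phosphorylation at 0.03 and ribosomal proteins at 0.01 became -0.00 and -0.02 with TMM scaling, and with median-of-ratios scaling 0.01 and -0.01.

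**Figure D2:**
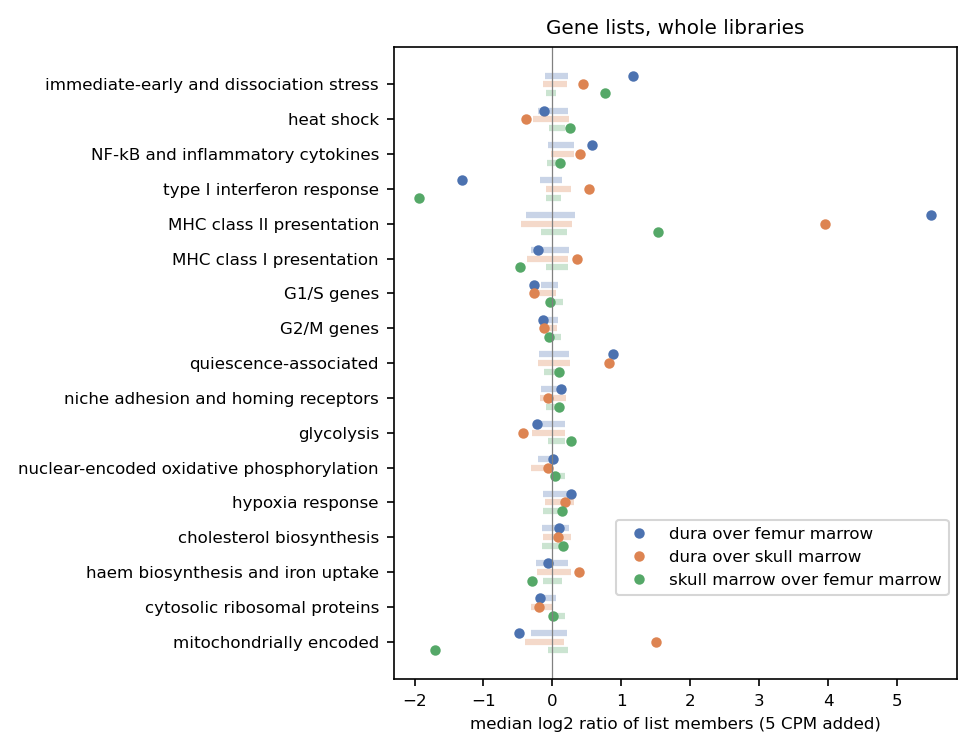
Median log2 ratio of each gene list for the 3 pairs of whole libraries, with pale bars for the range of random lists matched on expression. The interferon list lies at -1.31 for dura over femur and at -1.93 for skull over femur, and MHC class II at 5.50 and 3.96 for dura over femur and over skull, which are 0.10 and -0.11 with classes weighted equally.

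The skull library stood apart in sex-linked RNA. Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, were read at 30.6, 37.7, 8.70 and 6.83 CPM in skull and had no UMI in dura and femur. Xist UMIs without Y-linked UMIs were found in 84.0% of dura cells, 97.1% of femur cells and 0.0947% of skull cells. Y-linked UMIs without Xist were found in 57.0% of skull cells, 0 dura cells, which allows up to 0.144%, and 0 femur cells, which allows up to 0.0284%. Sex-linked RNA and mitochondrial share thus set the skull library apart in each comparison with it.

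Within HSC/MPP-like cells the femur library again held more interferon-stimulated RNA than both others. Isg15 stood at 420.0 CPM in femur (405 to 436), 33.8 CPM in dura (27.4 to 41.2) and 28.0 CPM in skull. Irf7 stood at 165 CPM in femur (156 to 175) and 10.0 CPM in dura (6.70 to 14.4). Of 24 measured interferon genes, 21 were lower in dura and 24 were lower in skull than in femur, with medians of -2.08 and -2.32. Between dura and skull the median was 0.23 and no member reached 2-fold.

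In these cells Ifit1, Zbp1 and Rsad2 had log2 ratios of -3.17, -3.10 and -2.87 for dura over femur, and Ifit1, Iigp1 and Rsad2 had -4.05, -3.81 and -3.58 for skull over femur. Interferon genes lead cluster 7, which held 463 of the 1650 femur cells. Without cluster 7 the list's medians were -1.73 for dura and -1.77 for skull over femur.

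**Figure D3:**
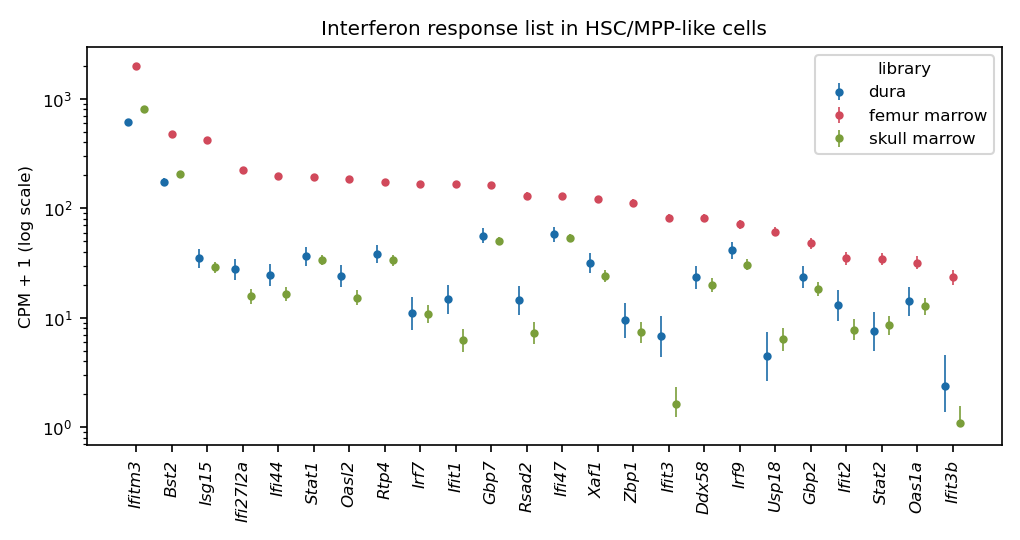
CPM plus 1, on a log scale, of each measured interferon gene in the HSC/MPP-like cells of each library, with exact Poisson 95% intervals. Of 24 genes, 21 were lower in dura and 24 in skull than in femur by at least 2-fold.

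Genes outside the interferon list also differed within HSC/MPP-like cells. Tmsb10, an actin-binding peptide, stood at 1366 CPM in dura, 512 CPM in femur and 589 CPM in skull. Erh had a log2 ratio of 1.15 for dura over femur and Dennd5b 1.31 for dura over skull. Hist1h1b and Hist1h2ap of the histone clusters had 1.59 and 1.52 for skull over femur, and Hist1h2ae had 1.48. Hist1h1b had -1.55 for dura over skull and Hist1h2ap 1.36 for dura over femur. Rps27rt (1.38 and 2.15 for dura over femur and skull) and the histone genes have near-identical copies, so their counts are uncertain. Xist stood at 1033 CPM in dura, 1537 CPM in femur and 0.206 CPM in skull (2 UMIs, 0.0250 to 0.745). Elane and Ms4a3 of granulocyte progenitors had -1.75 and -1.85 for dura over skull, and Junb had -1.28 for dura over skull and 1.42 for skull over femur. Ccl4, a chemokine that leads cluster 8, had -1.51 for dura over skull and 1.83 for skull over femur. With classes from each cell's marker score the log2 ratios of the histone genes, Ms4a3 and Elane moved by more than 1.5-fold, to 0.42 for Hist1h2ap, skull over femur, and -4.23 for Elane, dura over skull.

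Immediate-early genes in HSC/MPP-like cells had 10 of 20 members higher in skull than femur and 8 of 20 lower in dura than skull, with medians of 0.88 and -0.75, and a median of 0.12 for dura over femur. Mitochondrially encoded genes had medians of -0.38, 1.18 and -1.47 for dura over femur, dura over skull and skull over femur. MHC class I genes had medians of -0.46, 0.01 and -0.54. Over the other lists, the medians for those pairs lay between -0.51 for heat shock, dura over skull, and 0.42 for heat shock, skull over femur. In these, quiescence-associated genes had -0.05, 0.02 and -0.08, niche adhesion genes 0.03, 0.05 and -0.01, and hypoxia genes 0.27, 0.23 and 0.02. The last niche value became 0.00 with median-of-ratios scaling. With classes from each cell's marker score immediate-early genes turned to -0.01 and niche adhesion to -0.13 for dura over femur, and hypoxia to -0.05 for dura over skull, so no direction is read from medians this close to 0.

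Every other class compared with femur also held less interferon-stimulated RNA outside femur. Over 12 class comparisons with femur, HSC/MPP-like cells included, the list's median ran from -1.54 in monocyte lineage-like cells of dura to -2.43 in erythroid lineage-like cells of dura. Isg15 in monocyte lineage-like cells stood at 13.9 CPM in dura, 1.92 CPM in skull and 229 CPM in femur. In megakaryocyte lineage-like cells it stood at 10.3 CPM in skull and 215 CPM in femur, and in granulocyte-monocyte progenitor-like cells at 7.41 and 184 CPM. For dura over skull the list's medians were 0.03 in basophil lineage-like, 0.04 in erythroid lineage-like and 0.22 in monocyte lineage-like cells.

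Basophil lineage-like cells, all in cluster 2, differed in Prss34, Mcpt4, Tpsb2 and Cma1. Prss34, a basophil protease, stood at 12338 CPM in dura, 3886 CPM in skull and 1189 CPM in femur. Mcpt4, Tpsb2 and Cma1, which encode mast cell proteases, were higher in the dura cells: Mcpt4 stood at 1572 CPM in dura and 88.9 CPM in skull with no UMI in femur, at least 407-fold higher in dura than femur. Tpsb2, a tryptase, stood at 1061 and 38.9 CPM and was at least 274-fold higher in dura than femur, and Cma1, a chymase, stood at 1753, 136 and 78.6 CPM in dura, skull and femur. These genes left the class when interferon genes were left out of the clustering, which gave log2 ratios for dura over femur of 0.00 for Mcpt4, 0.18 for Tpsb2 and 0.15 for Cma1, and for dura over skull of -0.19 for Mcpt4 and -0.00 for Tpsb2. Prss34 then had 3.53 for dura over femur.

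T/NK/ILC-like and B lineage-like cells were compared between dura and femur. Il1rl1, the interleukin 33 receptor of innate lymphoid cells, stood at 324 CPM in dura T/NK/ILC-like cells with no UMI in femur, at least 13.7-fold higher. Lpcat2 was at least 9.87-fold higher. Sox4 stood at 4.61 against 473 CPM. Dura had 423 of its 569 cells in cluster 21, which Gata3 and Il1rl1 lead, and femur had 49 of its 50 cells in cluster 25, which Ccl5 and Gzma lead. In B lineage-like cells, Igha, an antibody heavy chain, stood at 3347 CPM in dura with no UMI in femur, at least 1031-fold higher, Jchain stood at 5276 against 149 CPM, and Ms4a1 at 314 against 7.57 CPM. These genes lead cluster 22, which held 57 of the 200 dura cells and 11 of the 287 femur cells. With classes from each cell's marker score Igha had a log2 ratio of 0.85 and Jchain one of -0.26. In the T/NK/ILC-like cells the median of all genes was -0.10 by CPM, 0.18 with TMM and 0.17 with median-of-ratios scaling.

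Erythroid, monocyte and granulocyte-monocyte progenitor-like cells lay partly in different clusters per library. Hbb-bs, a beta globin, stood at 4125 CPM in dura erythroid lineage-like cells, 3194 CPM in skull and 493 CPM in femur. Globin genes have near-identical copies and lead cluster 5, which held 61 of 111 dura cells, and cluster 31, which held 141 of 239 skull cells, while 848 femur cells lay in cluster 19. Granule RNA was also read in skull erythroid lineage-like cells, with Elane at 421 CPM against 1.99 CPM in dura and 44.2 CPM in femur. Without clusters 16 and 31 the skull over femur log2 ratio of Elane was 0.28 in place of 3.11, and that of Hbb-bs was 1.25 in place of 2.68. Part of the granule RNA remained without these clusters, as Prtn3 had 1.46, Ctsg 1.43 and Ms4a3 0.787. Elane was higher in skull basophil lineage-like cells too, at 1136 CPM against 337 CPM in dura and 405 CPM in femur. Whether this granule RNA came from the cells themselves or from free RNA was not tested. In monocyte lineage-like cells S100a4, a calcium-binding protein of mature monocytes, stood at 100.3 CPM in dura, 19.4 CPM in skull and 15.2 CPM in femur, and Ifitm1 at 123 CPM in dura, 349 CPM in skull and 120.2 CPM in femur. The globin Hbb-bs was also read there, at 122 CPM in dura, 11.8 CPM in skull and 10.9 CPM in femur. With classes from each cell's marker score its dura over skull log2 ratio was -0.085, and the source of this globin RNA was not tested. Dura cells of that class lay in clusters 11, 12 and 15, skull cells mostly in cluster 12 and femur cells in clusters 11 and 15, and with interferon genes left out of the clustering S100a4 had log2 ratios of 1.45 and 0.87 for dura over femur and skull in place of 2.38 and 2.11. In granulocyte-monocyte progenitor-like cells Camp stood at 108 CPM in skull and 5.11 CPM in femur, a log2 ratio of 3.49 that was 0.98 without cluster 16, and mitochondrially encoded genes had a median of -2.31, or -1.57 without it. The median of all genes for dura over femur in erythroid lineage-like cells was 0.03 by CPM and 0.15 with median-of-ratios scaling, and for dura over skull in monocyte lineage-like cells -0.15 and -0.04.

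Fewer cells of the dura library than of the marrow libraries carried RNA of dividing cells. A UMI of Mki67 or Top2a, which encode a proliferation antigen and a topoisomerase of mitosis, was found after thinning in 19.7% of dura cells (18.02 to 21.5), 48.8% of femur cells (47.8 to 49.8) and 38.8% of skull cells (37.0 to 40.6). The shallow cells left out numbered 59, 567 and 289, and the unthinned shares were 34.4%, 66.1% and 70.1%. Without clusters 16 and 31 the skull share was 43.7%. Without stromal-like cells and clusters 26 and 27 the dura share was 22.5% (20.5 to 24.5). Summed G1/S genes stood at 3108 CPM in dura, 3714 CPM in femur and 3729 CPM in skull, and summed G2/M genes at 6249, 6886 and 6620.3 CPM.

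Within HSC/MPP-like cells the thinned shares overlapped: 21.8% in dura (15.3 to 29.5), 25.9% in femur (23.7 to 28.3) and 25.1% in skull (21.7 to 28.8), with 0, 174 and 16 shallow cells left out and unthinned shares of 57.7%, 36.4% and 66.7%. Of T/NK/ILC-like cells, 2.84% were positive in dura (1.63 to 4.57) and 25.9% in femur (11.1 to 46.3, 23 of 50 left out). Of B lineage-like cells, 19.4% were positive in dura (14.1 to 25.6) and 87.0% in femur (81.7 to 91.3, 79 left out). Erythroid lineage-like cells had 74.1%, 69.0% and 48.2% in dura, femur and skull, and monocyte lineage-like cells 51.5%, 55.8% and 59.0%. Cluster 22, which antibody genes lead, was taken as a background. It had 0 positive of 55 dura cells at a median of 4061 UMIs, which allows up to 5.45%, and 0 of 5 femur cells at 1549 UMIs. In skull 3 of 13 cells were positive (5.04% to 53.8%) at a median of 3931 UMIs. Antibody genes do not show that cells had stopped dividing, so cluster 22 may hold dividing cells. The T/NK/ILC-like share of dura lies below the limit of 5.45%, so cluster 22 does not settle whether that share stands above background. The femur background, where 0 of 5 cells has an exact upper limit of 52.2%, and the skull background rest on too few cells to set a level. T/NK/ILC-like cells of dura had a median depth of 5398 UMIs, and HSC/MPP-like cells of skull one of 13709 UMIs.

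**Figure D4:**
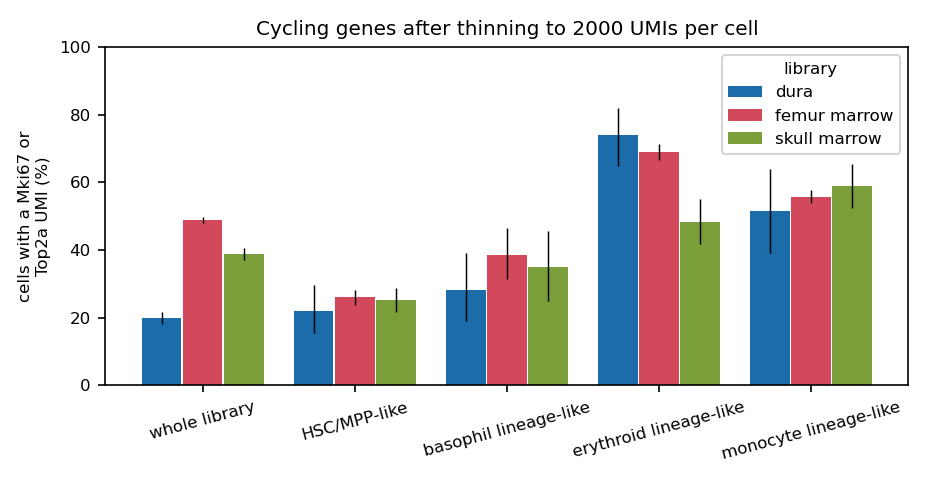
Percent of cells with a Mki67 or Top2a UMI after thinning to 2000 UMIs, for whole libraries and classes, with exact binomial 95% intervals. The whole dura library lies at 19.7% and the femur library at 48.8%, while the HSC/MPP-like values lie between 21.8% and 25.9%.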

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

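Barcodes under the gene minimum, which the comparisons leave out, held much globin RNA in 2 libraries. Globin genes made up 42.9% of their UMIs in dura, 23.6% in femur and 1.24% in skull. These values stand above the limit that a count of 0 allows, and their source was not tested.

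Of the tests of the interferon pattern, only the one on the mix of classes was chosen after the result was seen. Interferon-stimulated genes were higher in the femur library than in dura and skull. A different mix of cell classes would leave the within-class medians between -0.5 and 0.5, but over 12 class comparisons with femur the median closest to 0 was -1.54, which argues against it. A small set of strongly responding cells is also argued against, since 54.9% of thinned femur cells held more than 4 UMIs of the list, against 11.1% of dura and 8.48% of skull cells. The cut of 4 UMIs was the 90% point of the skull cells, so the low skull share was set by the cut. The state of the animals or handling of the femur pool cannot be told apart from the site, because there was 1 femur pool, so a difference of the femur site remains a hypothesis that these libraries do not test.

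Of the tests of skull cluster 16, only the one on doublets was chosen after the result was seen. Cluster 16 held 996 skull cells that carried granule genes, with 0.0477% of UMIs from Malat1 and 0.157% mitochondrial, against 0.401% and 0.987% in skull clusters 13 and 23. Free RNA in droplets without a cell would vary little between barcodes. The median variance over mean was instead 3.41, over 8 granule-stage markers, in the 793 cells of cluster 16 deep enough for thinning. In clusters 13 and 23 it was 1.69 over 13 markers, so the marker sets differ and the size of that contrast is not read. The value for cluster 16 argues against free RNA as the source of all its thinned barcodes. Shallower barcodes were left out, and a value over the whole set cannot show that each barcode held a cell. Free RNA in part of cluster 16 therefore stays open. Doublets would be deep, but the median depth of cluster 16 was 0.371 of the library's median. Cells that lost nuclear and mitochondrial RNA, such as fragments, could have given the pattern: 8 nuclear transcripts had a median log2 ratio of -0.48, between the bounds set for and against it, with Neat1 at -2.13 and Kcnq1ot1 at -3.26 but Pvt1 at 0.46. That explanation stays open, and no biological explanation was tested.

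Of the tests of the sex-linked RNA, those on pools of both sexes, on carried cells and on an exchanged dura label were chosen after the result was seen. Y-linked RNA was found in the skull library and Xist RNA in the dura and femur libraries. Pools of both sexes would leave cells of the other sex in each library, but at most 0.0947% of the cells of a library carried the RNA of the other sex alone, which argues against them. Cells of the skull pool carried into the dura library would bring Y-linked RNA. Of the 255 HSC/MPP-like, granulocyte-monocyte progenitor-like and cluster 18 cells of dura, 0 held it without Xist, with an exact upper limit of 1.44%, and 96.1% held Xist alone. Since 49.6% of the skull cells of these classes held Y-linked RNA alone, the share of cells carried from that pool could lie above that limit, but they do not account for most of these dura cells. Skull marrow cells of the mice that gave the dura would carry the same sex-linked RNA as the dura. This test cannot detect them, so it draws no conclusion about them. An exchange of the dura label with a marrow label would put Ttr of the choroid plexus and Ptgds of the meninges in a marrow library, but the lower limit of both in dura was at least 477 times the upper limit in each marrow library. Both genes lead those named as higher in dura in these same libraries, so the size of that ratio was set by their choice. Only the tissues in which these genes are known bear on the label. Exchanged skull and femur labels, or a library from other animals under a site's name, cannot be told apart, since there was 1 library per site. A candidate explanation is that the skull pool came from male animals and the others from female animals, in which case sex and site are confounded in every comparison with skull. Pools of the same animals would share their sex-linked RNA, so these values conflict with a reading of the labels in which the same 10 mice gave all 3 pools.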

How the results depend on the processing

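No paired analysis was possible because each site gave 1 library, and there were no replicates to leave out, so every value was set against its counting interval alone. Over all alternatives, class shares stayed within that interval in 191 cases and moved beyond it in 169. A change of direction was counted only for values of at least 2-fold as reported, so smaller values that changed sign count as moved. For list medians of whole libraries 261 stayed, 265 moved and 1 changed direction, and within classes 1299 stayed and 435 moved. For named genes of whole libraries 284 stayed, 330 moved and 6 changed direction, and within classes 696 stayed, 319 moved and 5 changed direction. Of the 284 that stayed, 60 came from the setting with no minimum for list members, which cannot change the ratio of a single gene. Leaving out stromal-like cells and clusters 26 and 27 likewise could not change class shares in femur, which had none of those cells. These counts therefore overstate how many results were stable. For cycle shares 4 stayed and 8 moved. Except where a setting's own construction shows it, the cause was not tested. The HSC/MPP-like share was 14.0% in femur and 11.2% in skull with all barcodes, 9.72% in femur with at least 1000 genes and at most 5% mitochondrial UMIs, and 12.6% in femur with no doublets removed. It was 8.46% in dura and 19.1% in femur at resolution 0.5, 14.1% in femur and 16.6% in skull at resolution 2, and 14.3% in femur with cycle genes kept. It was 5.62%, 1.92% and 15.3% in dura, femur and skull with equal cells per library, 4.52%, 13.9% and 9.35% with each library clustered alone, and 4.61%, 8.25% and 11.5% with classes from each cell's marker score. The T/NK/ILC-like share of dura was 23.7% with all barcodes. The dura over femur interferon median was -1.45 with TMM, -1.45 with median-of-ratios scaling, -1.41 with 1 CPM added and -1.69 with classes weighted equally. The skull over femur interferon median was -2.21 with 1 CPM added, -2.17 as means over cells, -1.84 with the stricter cell filter and -2.08 with classes weighted equally. Within HSC/MPP-like cells it was -2.29 for dura and -2.45 for skull over femur with 1 CPM added. The dura over skull MHC class II median was 3.79 with TMM, 3.77 with median-of-ratios scaling, 4.02 with 1 CPM added, 3.44 as means over cells, 4.004 with no doublets removed and -0.11 with classes weighted equally, a setting that gives the dendritic-like cells of dura no weight because skull has too few. That setting also turned H2-Ab1 (-0.15), Ckb (-0.17) and Plbd1 (-0.091) for dura over femur, and H2-Eb1 (-0.077), Cd74 (-0.16) and H2-Aa (-0.013) for dura over skull. Classes from marker scores turned Jchain in B lineage-like cells of dura over femur (-0.26), and for dura over skull Mcpt4 in basophil lineage-like (-0.10) and Hbb-bs in monocyte lineage-like cells (-0.085). The share of cells with a Mki67 or Top2a UMI was 13.8%, 33.1% and 26.2% in dura, femur and skull thinned to 1000 UMIs, 34.4%, 66.1% and 70.1% not thinned, and 50.4% in femur with no doublets removed. Of the alternatives chosen after seeing the data, leaving out clusters 16 and 31 gave a skull HSC/MPP-like share of 29.6%, a skull cycle share of 43.7%, an MHC class II median of 3.86 for dura over skull and an interferon median of -1.87 for skull over femur. Leaving out stromal-like cells and clusters 26 and 27 gave a T/NK/ILC-like share of 31.8% in dura and an MHC class II median of 4.06 for dura over skull. Leaving interferon genes out of the clustering gave a femur HSC/MPP-like share of 14.9% and turned Mcpt4 (-0.19) and Tpsb2 (-0.0042) for dura over skull in basophil lineage-like cells. Leaving out cluster 7 gave HSC/MPP interferon medians of -1.73 for dura and -1.77 for skull over femur. Rare classes rest on few cells: femur T/NK/ILC-like cells numbered 50.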

Other observations

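Other gene groups differed within classes, each between 1 library and another. In B lineage-like cells MHC class II genes had 4 of 6 measured members higher in dura than femur, with a median log2 ratio of 2.02. G2/M genes of mitosis had 14 of 52 members lower there, with a median of -0.82 that was -1.60 as means over cells, and NF-kB genes had 5 of 11 higher and 1 lower, with a median of 0.92. Dura held 108 of its 200 B lineage-like cells in cluster 3 and femur 275 of 287 in cluster 4. In T/NK/ILC-like cells MHC class II genes had 6 of 7 lower in dura than femur, with a median of -2.23 that was -0.97 with classes from each cell's marker score, G1/S genes had 17 of 37 lower and 1 higher, and G2/M genes had 15 of 36 lower. In monocyte lineage-like cells MHC class II genes had 4 of 7 higher in skull than femur and 3 of 7 lower in dura than skull, with medians of 1.06 and -0.93. With classes from each cell's marker score those medians were 2.79 and 1.2, so the latter changed sign, and the cause was not tested.

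MHC class I genes, which present peptides to cytotoxic T cells, had lower medians outside femur in erythroid lineage-like cells. There 7 of 10 were lower in dura, with a median of -1.30, and 4 of 10 in skull, with a median of -0.78. Immediate-early genes had medians of 0.74 in basophil lineage-like, 0.72 in granulocyte-monocyte progenitor-like and 0.75 in megakaryocyte lineage-like cells for skull over femur. For dura over femur they had 0.78 in B lineage-like, 0.92 in T/NK/ILC-like and 0.74 in basophil lineage-like cells. Mitochondrially encoded genes had medians from -2.31 in granulocyte-monocyte progenitor-like cells to -1.23 in megakaryocyte lineage-like cells for skull over femur, so the low mitochondrial RNA of the skull library was found in each class compared.

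Barcode sequences were shared more often between skull and femur than between dura and either. Dura and femur shared 8 barcodes, dura and skull 2, and skull and femur 61, where the rate of the dura pairs would give 15.04 (7.21 to 27.7, from the counting interval of that rate). The source of the difference was not tested.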
